A study of Drosophila melanogaster with 3 samples.

How the data were processed

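The series held 3 libraries of chromatin immunoprecipitation followed by sequencing, made from whole Drosophila melanogaster embryos aged 8 to 24 h. The embryos carried an insertion that targets HLH4C and fuses its protein to eGFP, per the labels. The labels disagree on the antibody: the sample descriptions give an antibody against GFP, which was followed here, and the antibody field names HLH4C. HLH4C is a basic helix-loop-helix (bHLH) transcription factor. Chromatin was fragmented by sonication with a size range of 200 to 800 bp, per the labels. The 3 libraries were numbered as biological replicates 1, 2 and 3 of a single group, so no comparison between conditions was possible. No input or untagged library was used here.

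The authors deposited peak lists, not reads. For each replicate there was a list of ranked peaks and a shorter thresholded list, both on assembly dm6 and derived from that replicate's alignments, per the text files deposited with each sample. The aligner, the peak caller and their settings were not given in the sources used here. Each deposited entry carries a signal value, 1 per peak, whose normalization was not given; it was used to rank and filter entries within a list and was printed as the authors' value. Each deposited entry also carries a score, and in the deposited ranked lists a −log10 value of the global irreproducible discovery rate (IDR). This is the estimated share of peaks that do not recur between inputs, among those ranked at least as high. In the ranked lists the score followed from the rate, on its logarithmic scale, to within 1 unit for 100% of entries. The lowest score in each thresholded list was 830, which corresponds to an IDR of 0.01. The depth in reads was unknown, because peak lists hold no read counts, so no depth-based limit is given. Intervals printed beside shares of peaks or genes cover counting error over those features, which are not independent replicates. Series-level lists were derived from the alignments of all 3 replicates together. Of these, the authors' conservative list and their largest thresholded list served as alternatives and are pooled values without an SD or n. The remaining series-level lists were not used here, since nothing tied their inputs to replicates.

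Peaks were kept on the 7 chromosome arms 2L, 2R, 3L, 3R, 4, X and Y, and 0 entries ran past the end of an arm in the Release 6 genome. Summits of the 3 thresholded lists were joined by single linkage when within 200 bp, and a cluster with all 3 replicates was called a reproducible peak, placed at its median summit. Strength was the mean, over the replicates, of the signal's percentile within its own list. Agreement between lists was set beside 100 seeded circular shifts of the other list along each arm. Summits were assigned to promoters when within 500 bp of an annotated transcript start of Ensembl release 115 (BDGP 6.54, transposable elements left out), then in order to 5′ UTR, coding exon, 3′ UTR, other exon, intron or intergenic sequence. Shares were tested against the share of sequenced bases with the exact binomial test. Sequence was scored as the presence of a site, on either strand, within 50 bp of the summit. It was compared with a window of the same size centred 500 bp away on a random side, with the exact McNemar test. This was done for CAGCTG, for all 10 classes of E-box (CANNTG, the bHLH site) and for all distinct 6-mers. The strongest 20% and weakest 20% of peaks were compared with Fisher's exact test. A gene was called bound when a transcript start lay within 1000 bp of a reproducible summit. Each of 19 gene lists was compared with all other protein-coding genes by Fisher's exact test. All tests were two-sided, and families of tests were adjusted by the Benjamini-Hochberg method at 0.05.

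The gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took HLH4C and its partner gene da, the nearest protein-coding gene of the 20 strongest reproducible peaks, and up to 5 bound members of each list that passed. It also took up to 2 bound members of every other list and the 10 6-mers with the highest ratio among those that passed and occurred at 5% or more of summits. Of 420 list entries, 2 were matched through older symbols and 3 were not matched and are not analysed here. Analyses of TATCGA and TATCGATA, of gene families outside the 19 lists and of peaks beside HLH4C, and tests of arms against transcript starts other than for X, were chosen after seeing the data. Alternatives varied the joining distance, the number of replicates needed, the peak list, the threshold, the windows, the flank, the promoter and binding distances and the background, and each replicate was left out in turn.

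The steps were tested on simulated data. In 1994 random windows with nothing planted, 0 6-mers passed. These windows were placed at random, so differences in base composition between promoters and their flanks were not simulated. A 6-mer planted in 5% of windows was recovered in 90% of trials, and 1 planted in 2% of windows in 5%. For lists of 30 genes, a bound share of 50% was called in 79.0% of trials, a share of 35% in 21.5%, and lower shares of 10, 5 and 0% in 1.5, 7 and 21.5%, so moderate differences in short lists were mostly out of reach. Joining recovered 1000 of 1000 shared simulated sites with 0 false ones. Distinct simulated sites lay farther apart than the joining distance, so false joins could not arise and crowded summits were not tested. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with matplotlib 3.10.9 for plots.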

Results

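HLH4C-eGFP was mapped by immunoprecipitation, with an anti-GFP antibody per the sample descriptions, in 3 biological replicates of whole embryos aged 8 to 24 h. HLH4C is a bHLH factor related to vertebrate NHLH1 and NHLH2, whose textbook site is the E-box CAGCTG. The thresholded lists held 3513 peaks in replicate 1, 2956 in replicate 2 and 2722 in replicate 3, a mean of 3064 ± 406 (SD, n = 3). They were drawn from 98039, 134344 and 126139 ranked peaks. The median of the authors' signal value per peak was 85.8, 97.8 and 86.3 in replicates 1, 2 and 3. The number of reads behind these peaks was unknown. No entry was identical between lists, with 0 shared combinations of position and signal.

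The first question was how far the replicates recovered the same sites. A total of 1924 peaks had summits in all 3 replicates, out of 4060 clusters of summits, and 2575 clusters held at least 2 replicates. The summits joined in a reproducible peak had a median spread of 35 bp, and in 306 of the 1924 peaks they spanned over 200 bp, which single linkage allows. The share of a list with a summit of another replicate within 200 bp ranged from 66.0%, for replicate 1 against replicate 3, to 83.5%, for replicate 3 against replicate 1. Circular shifts of the other list gave mean shares between 0.768% and 1.03%. The highest share in any shift was 12.8%, in a draw that moved arm 3L by only 177 bp, less than the joining distance. Leaving out shifts under 1000 bp, the highest was 1.55%. The shifts did not keep summits at transcript starts, so the share for unrelated lists of promoter summits was not measured. Across the 1924 peaks, Spearman's rho of the signal was 0.841 between replicates 1 and 2, 0.841 between replicates 1 and 3 and 0.894 between replicates 2 and 3, computed over peaks, which are not independent replicates. Clusters confined to a single replicate numbered 839 in replicate 1, 421 in replicate 2 and 225 in replicate 3. The count of peaks depended on the list, and the authors' conservative series list held 3759 summits on the arms and their largest list 5144. Of the 1924 reproducible peaks, 99.5% lay within 200 bp of a summit of the conservative list.

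Binding was concentrated at transcript starts. Of the 1924 reproducible summits, 1754 (91.2%, exact 95% interval 89.8 to 92.4%) lay within 500 bp of an annotated start, where 13.3% of bases lie. This was a 6.85-fold excess, and the exact binomial p-value was too small for double precision to hold. The single replicate lists gave 85.2 ± 2.17% (SD, n = 3). Promoter summits sat just upstream of the start, at a median of -40 bp with quartiles at -79 and -11 bp, and 80.3% were upstream. Introns held 4.57% of summits against 39.2% of bases (exact binomial adjusted p = 4.62e-278), and intergenic sequence 3.22% against 28.2% (adjusted p = 4.38e-184). Coding exons held 2 of the 1924 summits.

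**Figure D1:**
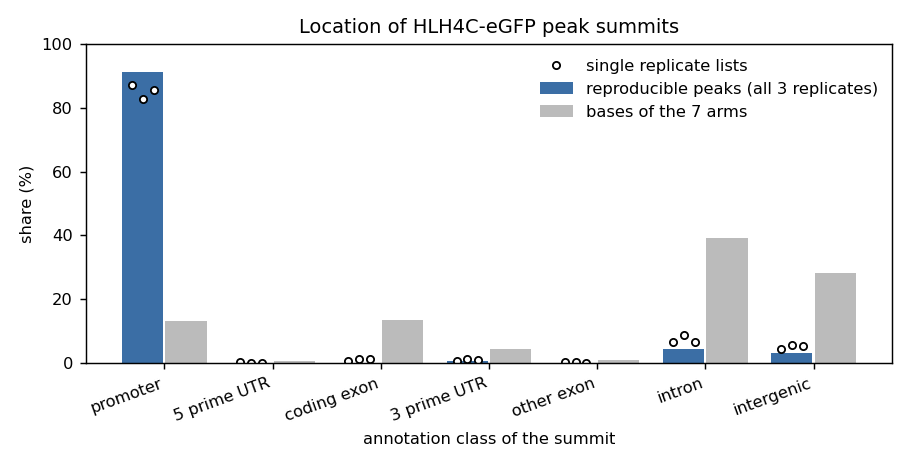
Share of summits (y axis, %) in each annotation class (x axis), for the 1924 reproducible peaks (blue bars), the bases of the 7 arms (grey bars) and each replicate list (open points). Promoters hold 91.2% of reproducible peaks and 13.3% of bases.

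Peaks were distributed unevenly over the chromosomes. Chromosome X held 406 reproducible peaks, 21.1% of the total against 17.1% of bases (exact binomial adjusted p = 2.24e-05) and 16.5% of transcript starts (adjusted p = 9.91e-07), and 19.8 ± 0.857% of the replicate lists (SD, n = 3). Arm 2R was also above its share of bases, with 20.5% against 18.4% (exact binomial adjusted p = 0.0353), but it held 20.55% of transcript starts, and against these its share did not differ past the threshold (adjusted p = 1). Arm 3L was below both, with 17.0% of peaks against 20.4% of bases (exact binomial adjusted p = 0.000439) and 19.2% of starts (adjusted p = 0.0410). No reproducible peak lay on Y, 0 against 2.49% of bases (exact binomial adjusted p = 1.34e-20) and 0.477% of starts (adjusted p = 0.000649). The ranked lists of replicates 1, 2 and 3 held 66, 236 and 199 entries on Y, and the thresholded lists 0. How much of Y reads could be placed on was not measured, so the lack of peaks there does not show a lack of binding. Shares of 2L, 3R and 4 passed neither test. In the authors' largest series list the X share was 17.6%, no longer past the threshold.

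Of the 20 strongest peaks, 19 lay at promoters, and the exception was in an intron of org-1, a T-box gene, 2494 bp downstream of its start. The peak with the highest strength was at Ube3a (FBgn0061469), an E3 ubiquitin ligase gene, with its summit at 3L position 11210646 in dm6, 63 bp upstream of the start (-63). Its authors' signal was 807, 1052 and 923 in replicates 1, 2 and 3. Next came Alms1a (FBgn0025388; X, 4636066; -62 bp), a centriole gene, with signals of 684, 828 and 872, and MESK2 (FBgn0043070; 2R, 21501996; -101 bp), with 858, 825 and 616. Others among the 20 strongest were STUB1, a ubiquitin ligase gene, hts, which encodes adducin, and milt, which encodes an adaptor for mitochondrial transport. The proteasome subunit gene Rpn6 had its summit at 2R position 14752368, at -97 bp. The ribosomal protein gene RpL32 had its summit at 3R position 30046231, at -70 bp. The remaining names were mRpL30, CG13766, Capr, kug, Cbp80, Creld, CtsF, RhoGAP93B, Fit2, NAT1 and shtd. Mean within-list percentiles of the 20 ran from 99.3 ± 0.264 at shtd to 99.99 ± 0.0164 at Ube3a (SD, n = 3). Of the 20, 17 were upstream of the nearest protein-coding start, and 1 more, at Capr, lay equally far from 2 of its starts, upstream of one and downstream of the other.

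HLH4C itself met the definition of a bound gene, through a peak centred on its neighbour. The gene (FBgn0011277) spans X positions 4645127 to 4647414 on the minus strand, and the nearest summit, at 4647881, lay at -467 bp from its start. That summit also lay at 10 bp into mRpL30, a divergently transcribed mitochondrial ribosomal protein gene. Its authors' signal was 613, 730 and 766 in the 3 replicates. In all, 3 of the 20 strongest peaks lay within 10 kb of HLH4C, the other two at Alms1a and Cbp80. The gene da (FBgn0267821), whose product is the common partner of bHLH factors, was not bound, and the nearest summit to one of its starts lay 15903 bp away.

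**Figure D2:**
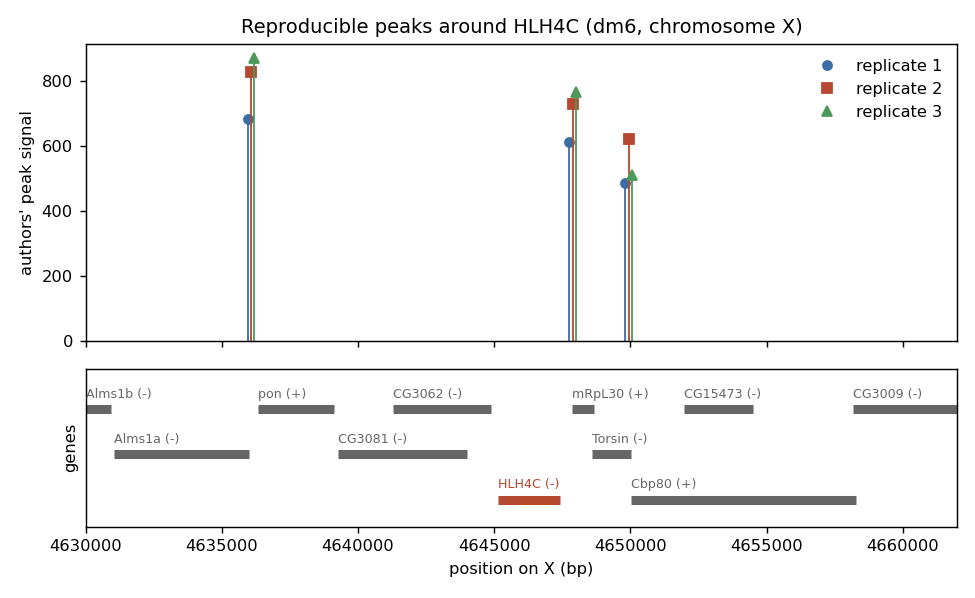
Authors' peak signal (upper panel, y axis) of reproducible peaks in each replicate, with lines offset by 120 bp for visibility, against position on X in bp (x axis); genes with their strand are drawn in the lower panel, HLH4C in red. The 3 peaks, at Alms1a, mRpL30 and Cbp80, have signals from 488 to 872.

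The main question of sequence was whether the CAGCTG E-box marked the summits. CAGCTG occurred within 50 bp of 7.85% of reproducible summits and in 5.25% of flanking windows, a difference of 2.60 percentage points (exact McNemar p = 0.00137). The replicate lists gave 7.64 ± 0.575% at summits and 5.24 ± 0.379% at flanks (SD, n = 3), and the difference was in the same direction in all 3. It was 0.520 points and did not pass with a window of 25 bp (exact McNemar p = 0.403), and 1.61 points with a flank at 1000 bp (p = 0.0561). With a window of 100 bp it was 3.74 points (exact McNemar p = 0.000501). Against the summit windows' own sequence with dinucleotides shuffled it was 6.39 points (exact McNemar p = 9.22e-23). Flanking windows were not set against their own shuffles, so the shuffled comparison does not show that CAGCTG is particular to summits. Among the 10 E-box classes CAGCTG alone passed with a higher share at summits (exact McNemar adjusted p = 0.00458). With the flank at 1000 bp 0 classes passed as higher. The same held with the stronger 50% of each list by signal, where the CAGCTG difference was 1.64 points (exact McNemar p = 0.121). CACATG, at 3.12% against 5.93% (exact McNemar adjusted p = 0.000233), CACCTG, at 2.65% against 5.93% (adjusted p = 7.52e-06), and CATATG, at 1.46% against 2.96% (adjusted p = 0.00483), were lower. Any E-box occurred at 34.9% of summits and 40.7% of flanks (exact McNemar p = 0.00034). Summit windows were less rich in G and C, 40.3% on average against 45.3% at flanks.

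The scan of all 6-mers found another sequence at most summits. TATCGA, the core of the DNA replication-related element TATCGATA, the textbook site of the factor DREF, occurred at 56.3% of reproducible summits and 3.69% of flanks, a 15.3-fold ratio, and the difference of 52.6 points was 27.4 points in the authors' largest list. The 6-mers CGATAG, at 45.5% against 2.65% (exact McNemar adjusted p = 1.05e-209), and ATCGAT, at 51.8% against 3.79% (adjusted p = 9.92e-234), had similar ratios. The others of the 10 named 6-mers were ACTATC, CGATAA, ATATCG, CGATAC, GATAGC, CCGATA and GATAAC. Of the 10, 9 contained GATA on 1 strand. At least 1 of the 10 was present at 77.5% of summits and 20.2% of flanks. In total 273 of the tested 6-mers passed as higher at summits and 569 as lower. The scan did not correct for the lower share of G and C at summits, so these counts may partly reflect base composition. The full TATCGATA occurred at 25.7% of summits and 0.520% of flanks (exact McNemar p = 3.58e-135). In the replicate lists TATCGA was present at 43.6 ± 4.31% of summits and 4.12 ± 0.357% of flanks (SD, n = 3). Sites were centred on the summits, with a median distance from the summit to the nearest TATCGA of 25.5 bp among the 1589 peaks with a site within 500 bp. For CAGCTG this distance was 180.5 bp, among 846 peaks. At the Alms1a promoter the sequence CCTTTGTTATCGATATCGAT (X, 4636055 to 4636074, plus strand) lay under the summit. At the promoter shared by HLH4C and mRpL30 the sequence beside the summit was CTGCCCATCGATAGGCAACT (X, 4647845 to 4647864, plus strand). The promoter of CtsF, a cathepsin gene, had CGGTAAGTATCGATAGCCTT (3R, 5251787 to 5251806, plus strand). Of the 20 strongest peaks, 11 had TATCGA and 0 had CAGCTG.

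**Figure D3:**
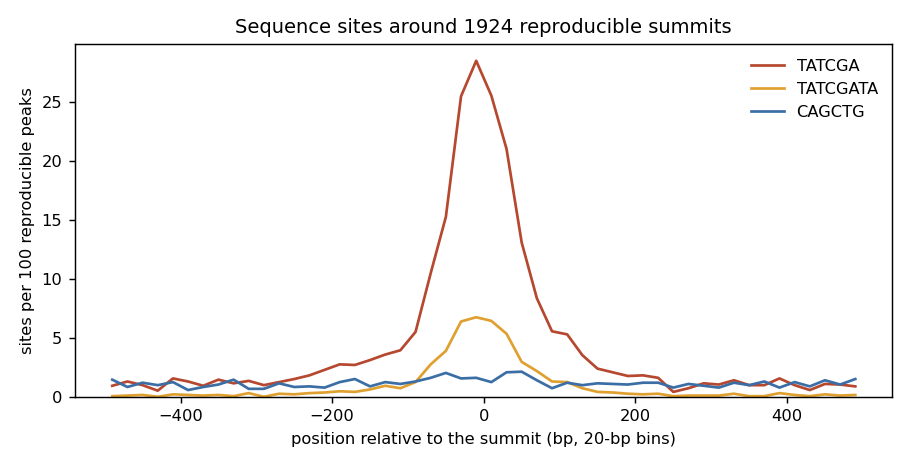
Sites per 100 reproducible peaks (y axis) in bins of 20 bp against position relative to the summit in bp (x axis), for TATCGA, TATCGATA and CAGCTG. TATCGA and TATCGATA peak at the summit, and CAGCTG, on the same scale, ranges from 0.572 to 2.13 sites per 100 peaks, with its highest bin centred 50 bp from the summit.

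Strong peaks were compared with weak ones. Of the strongest 20% of the reproducible peaks, 96.6% of 384 were at promoters, against 83.3% of the weakest 20% (Fisher's exact p = 4.70e-10). TATCGA was present at 64.6% of the strong and 40.1% of the weak peaks (Fisher's exact p = 1.46e-11). CAGCTG was present at 5.21% of the strong and 8.33% of the weak peaks, which did not pass (Fisher's exact p = 0.113), and passed without replicate 3 (difference -3.89 points). Without replicate 1 the CAGCTG difference was -0.714 points (Fisher's exact p = 0.769), and in the lists of replicates 1, 2 and 3 it was -0.997, -0.681 and -3.51 points. TATCGATA, at 24.5% and 21.4%, did not differ past the threshold (Fisher's exact p = 0.345). Without replicate 2 the TATCGATA difference was 10.1 points and without replicate 3 it was 7.32 points, both past it. Within each replicate list TATCGATA was more frequent in the strongest 20%, by 24.4, 13.5 and 21.3 points in replicates 1, 2 and 3. The thresholded lists of replicates 1, 2 and 3 held 435, 217 and 222 entries that overlapped a stronger one. These were kept, and their effect on comparisons within a replicate list was not tested. Without such entries the TATCGA difference among reproducible peaks was 24.3 points. Within the replicate lists the difference between strong and weak peaks was 54.6, 41.2 and 46.8 points for TATCGA and 16.5, 25.7 and 19.6 points for promoters. In the authors' conservative list it was 56.6 points for TATCGA and 39.0 for promoters, and in their largest list 56.9 and 43.3. Neither difference passed when only the stronger 50% of each list by signal was used, at 7.76 points for TATCGA and 3.88 for promoters.

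Of 13968 protein-coding genes, 2622 (18.8%) had a start within 1000 bp of a reproducible summit. Among the 19 lists, 1 passed with a higher bound share, the ribosomal protein genes, with 33 of 92 bound (35.9%, exact 95% interval 26.1 to 46.5%) against 18.7% of other genes (Fisher's exact odds ratio 2.44, adjusted p = 0.00239). The 5 with the strongest peaks were RpL32, RpS2, RpS30, RpS10b and RpS7, with mean within-list percentiles of 99.4 ± 0.230, 96.5 ± 1.98, 93.0 ± 0.897, 91.8 ± 2.07 and 91.5 ± 2.10 (SD, n = 3). With the stronger 50% of each list by signal, 21 of the ribosomal protein genes were bound and the list did not pass. It passed with 53 bound when starts within 5000 bp were counted, and with 61 bound in the authors' largest list.

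No list of neural or other developmental genes passed in either direction, though 2 lists were lower at an unadjusted p under 0.05 by Fisher's exact test and 5 against random lists matched on number of starts and gene length. The lowest adjusted p against matched lists was 0.0545, for both the bHLH factor and the neurotransmitter genes. Of the bHLH factor genes 2 of 42 were bound (4.76%; Fisher's exact p = 0.0162, adjusted p = 0.150), HLH4C and tgo, and of the neurotransmitter genes 0 of 22 (Fisher's exact p = 0.0237, adjusted p = 0.150). The neurotransmitter list passed when 2 of 3 replicates were required (Fisher's exact adjusted p = 0.0412) and in the authors' conservative list (Fisher's exact adjusted p = 0.0230), with 0 bound in both, and had 2 bound in the largest list (adjusted p = 0.0969). The bHLH count passed under none of these, with 6 bound in 2 of 3 replicates (Fisher's exact adjusted p = 0.564), 8 in the conservative list (adjusted p = 0.571) and 10 in the largest (adjusted p = 0.616), and it was 4 without replicate 2 and 4 without replicate 3. Bound members were 4 of 32 pan-neuronal genes, among them the adhesion gene Nrg and the potassium channel gene slo, and 7 of 33 axon guidance genes, among them Nrg and the netrin receptor gene fra. Among 30 neuropeptide and secretory genes 4 were bound, including Lk and the amidating enzyme gene Phm. The Notch pathway and E(spl) list had 5 of 30, including mam and gro, and the neuroblast and temporal list 1 of 25, brat. Neuronal identity factors had 3 of 35, including exd and ey, glia 3 of 16, including Cont and loco, and peripheral sensory organ genes 1 of 23, nan. Outside the nervous system, muscle had 2 of 29, Mef2 and Tm1, haemocyte and fat body 3 of 18, including Pvr and Hml, and epidermis and cuticle 1 of 20, tyn. Trachea had 1 of 14, tgo, germline 1 of 13, tud, heat shock 2 of 14, Hsp68 and Hsp83, endoderm and gut 0 of 13 and Hox 0 of 8. Several of these calls came from a peak nearer to a neighbouring gene. The summit assigned to Lk was nearest to CG34039, that of slo to Ppox, that of Hsp68 to SMC1 and that of Hsp83 to CG14965. Summits assigned to nan, Tm1 and HLH4C were nearest to nuf, MRG15 and mRpL30. Simulated lists of 30 genes passed in 21.5% of trials at a bound share of 35%, in 7% at a share of 5% and in 21.5% with 0 members bound, so most differences of these sizes would be missed in lists of this length.

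**Figure D4:**
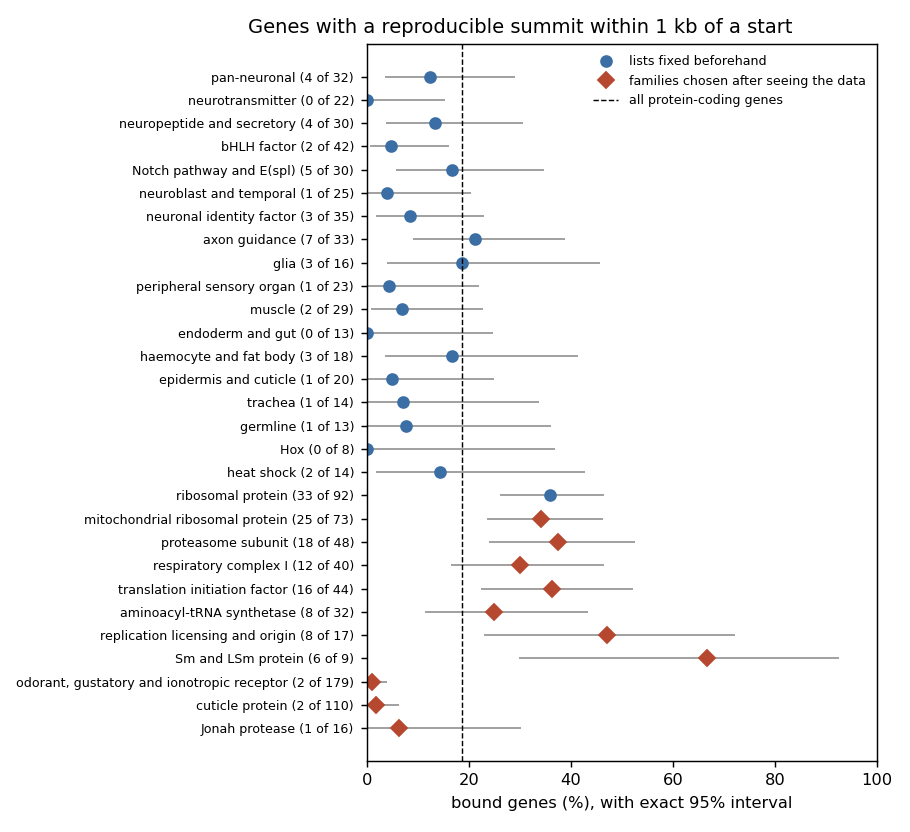
Share of genes bound (x axis, %, with exact 95% intervals over genes) for each gene group (y axis, with bound and total members). Circles are the 19 lists fixed beforehand, diamonds are 10 families chosen after seeing the data, and the dashed line is the 18.8% of all protein-coding genes.

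Transfer RNA genes were bound more often than protein-coding genes, and small nuclear and nucleolar RNA genes less often. The comparison was planned because highly transcribed genes can be recovered in any immunoprecipitation. Without an input or untagged library, such recovery could not be told from binding by HLH4C. Of 290 tRNA genes 134 (46.2%) had a reproducible summit within 1000 bp of a start, against 18.8% of protein-coding genes (Fisher's exact odds ratio 3.72, adjusted p = 2.38e-25). This excess of 27.4 points was 8.53 points with the stronger 50% of each list by signal, still past the threshold. Those genes are clustered, and 79 peaks accounted for them. Of 301 snRNA and snoRNA genes 34 (11.3%) were bound (Fisher's exact odds ratio 0.551, adjusted p = 0.000714), a difference of -7.48 points that was -12.7 in the authors' largest list. Of the 29 peaks within 1000 bp of an snRNA or snoRNA start, 10 lay within 200 bp. Neither comparison was matched on number of starts per gene, so differences in annotation were not separated from differences in binding. Within 200 bp of a tRNA start there were 75 peaks, at a median of 57 bp. TATCGA was present at 1 of them (1.33%), against 58.5% of all other reproducible peaks (Fisher's exact p = 1.70e-26).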

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

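Outside the 7 arms, the thresholded lists of replicates 2 and 3 held 20 and 13 peaks on unlocalised scaffolds of chromosome X, a signal in sequence that no comparison used and above the 3 that a count of 0 allows. Replicate 1 held 3. In the paragraphs that follow, the patterns other than the X share, which was a planned comparison, and the tests of all explanations were chosen after the peak lists had been seen, and each bound was set before its test was run, except where stated.

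TATCGA marked 56.3% of summits of a bHLH factor, where CAGCTG marked 7.85%. If any active promoter were recovered whatever its sequence, ribosomal protein genes without TATCGA near a start would be bound as often as other genes with it. They were bound in 9.52% of 42 cases (exact 95% interval 2.66 to 22.6%), against 40.4% of 4683 other genes with TATCGA. Within the ribosomal protein list, 58.0% of 50 genes with TATCGA were bound. This met the outcome set beforehand against that explanation. It does not decide, because TATCGA was chosen from these same summits and the activity of the 42 genes was not measured. Genes for tRNA were bound almost without TATCGA. A library from another line stays open: the weak peaks within 20 kb of HLH4C lay at the 84.9, 47.1 and 94.6 percentiles of random windows in replicates 1, 2 and 3. This met the outcome set beforehand for such a library, the 95 percentile or less in at least 2 replicates, but a correct library without extra copies would give unraised weak signal too, so it was judged, after the values were seen, not to decide. Of the 20 strongest peaks, 3 lay within 10 kb of the tagged gene, which was weighed after it was seen. Of 13968 protein-coding genes, 3 (0.0215%) had as many, HLH4C and its neighbours CG3081 and CG3062, which count the same peaks. No biological explanation was tested, since the design has 1 group. Recruitment of HLH4C by a factor bound at TATCGA, or cross-linking at such promoters in any GFP line, cannot be separated without another GFP line. Neither such a line nor an untagged library was used here. The labels name both GFP and HLH4C as the target of the antibody, and this bears on the explanation by cross-linking.

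The strong peaks at Alms1a, mRpL30 and Cbp80 lie around the tagged gene. If extra copies of the region raised them, weak peaks within 20 kb would be raised as well. Their median signal lay at the 84.9, 47.1 and 94.6 percentiles of 10000 random windows in replicates 1, 2 and 3, a mean of 75.5 ± 25.1 (SD, n = 3). All 3 met the outcome set beforehand against extra copies, the 95 percentile or less. The highest, 94.6, is under that bound by less than the spread between replicates, and it was judged after the values were seen that extra copies and strong binding cannot be told apart here. Weak signal may also miss extra copies if the authors' normalization divides by a control that carries them. No biological explanation was tested.

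The excess on X may follow in part from promoter sequence. Of 1357 protein-coding genes with TATCGATA within 200 bp of a start, 23.4% were on X, against 15.7% of all protein-coding genes, and this reached the lower bound of the X share of peaks (19.3%). Among genes with TATCGATA, 62.8% were bound on X and 67.2% on the other arms. Genes without TATCGATA were bound in 17.7% of cases on X and 12.97% elsewhere, so TATCGATA at promoters does not account for the whole excess. Of all bound genes, 20.3% were on X. Reaching the bound does not show how much of the excess TATCGATA accounts for. Depth and copy number were not tested, and no biological explanation was tested.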

How the results depend on the processing

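The promoter share, the TATCGA share at summits, the count of 6-mers and both non-coding RNA comparisons kept their direction and call, or for the count stayed within 1.5 times, under every alternative run, though sizes moved. Their ranges were 73.1 to 94.5% for promoters, 27.4 to 59.4 points for TATCGA, 222 to 318 6-mers, 8.53 (stronger 50%) to 37.5 points (conservative list) for tRNA genes and -12.7 to -7.17 points for snRNA and snoRNA genes. The planned stricter threshold of IDR 0.01 equals the authors' threshold and moved nothing, so it says nothing about stability. The stronger 50% of each list by signal, IDR 0.05, the removal of entries overlapping a stronger one, and all alternatives for TATCGA, for TATCGATA and for promoters by strength were chosen after seeing the data. The number of reproducible peaks was 3759 and 5144 in the authors' conservative and largest lists, which pool replicates, and 1161 with the stronger 50%. The X share was 17.6% in the largest list. The CAGCTG difference was 0.520 points with a window of 25 bp, 1.61 with a flank at 1000 bp and 1.64 with the stronger 50%, no longer past the threshold, and 0 E-box classes were enriched under the last pair. It passed under the other alternatives run. The highest, 6.39 against shuffled windows, does not compare summits with other places in the genome. With the stronger 50%, which removes the weak peaks, the differences between strong and weak peaks were 3.88 points for promoters and 7.76 for TATCGA, neither past the threshold, -2.16 for TATCGATA, the reverse of its direction, and -6.03 for CAGCTG, past it; 0 lists were enriched and 21 ribosomal protein genes were bound. Under the other alternatives the promoter and TATCGA differences passed, up to 43.3 points for promoters and 56.9 for TATCGA in the largest list. The CAGCTG difference by strength also passed at IDR 0.05 (-4.32) and with the peaks cut into 3 equal parts (-3.74), and ranged from -3.89 to -0.714 when 1 replicate was left out. The TATCGATA difference by strength passed with 2 of 3 replicates (11.7), the conservative list (23.0), the largest list (25.8) and IDR 0.05 (8.41), and ranged from 5 to 10.1 without 1 replicate, passing when replicate 2 or replicate 3 was left out. With 2 of 3 replicates and with the conservative list, 1 gene list passed with fewer bound members. The count of ribosomal protein genes bound ranged from 21 to 61 over the alternatives. Except where stated, the cause was not tested. Read depth was unknown, so its limit on weak peaks could not be set. No paired analysis was possible because the design has 1 group.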

Other observations

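The gene families in this part, the divergent promoters, the genomic sites and the combined neural list were all chosen after seeing the data. The families were picked after the strongest peaks, Rpn6 and mRpL30 among them, had been seen, so their tests are not independent evidence. Of 10 families defined by gene symbol, 5 passed with a higher and 2 with a lower bound share (Fisher's exact test, Benjamini-Hochberg over the 10). Proteasome subunit genes had 18 of 48 bound (37.5%, Fisher's exact adjusted p = 0.00472), led by Rpn6, Prosalpha7 and Rpn10. Mitochondrial ribosomal protein genes had 25 of 73 (34.2%, Fisher's exact adjusted p = 0.00472), led by mRpL30 and mRpL42, and translation initiation factor genes 16 of 44 (36.4%, Fisher's exact adjusted p = 0.00954), led by eIF3f1 and eIF2gamma. Replication licensing and origin genes had 8 of 17 (47.1%, Fisher's exact adjusted p = 0.0105), among them Mcm5, geminin and Orc6, and Sm and LSm genes of the splicing machinery 6 of 9 (66.7%, Fisher's exact adjusted p = 0.00472), among them SmB, SmE and SmD3. Summits assigned to Mcm5 and SmB were nearest to the neighbouring genes Art1 and KdelR. Respiratory complex I genes, with 12 of 40 (Fisher's exact adjusted p = 0.126), aminoacyl-tRNA synthetase genes, with 8 of 32 (adjusted p = 0.365), and Jonah protease genes, with 1 of 16 (adjusted p = 0.365), did not pass. Odorant, gustatory and ionotropic receptor genes had 2 of 179 bound (1.12%, Fisher's exact adjusted p = 1.00e-12), and cuticle protein genes 2 of 110 (1.82%, Fisher's exact adjusted p = 2.77e-07). Against 10000 random lists matched on number of starts and gene length, 5 families were again higher and 2 lower.

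The 10 neural, bHLH and Notch lists together had 29 of 273 genes bound (10.6%), against 18.9% of other genes. The shares were 17.2% and 26.9% in the authors' conservative list and 30.04% and 33.7% in their largest list. No test is given, since the lists were combined after their shares had been seen. Of the 19 single lists, 17 had a bound share below that of other genes.

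Bound promoters were often shared by a pair of genes. Of 5052 protein-coding genes with a divergent start within 1000 bp, 34.7% were bound, against 9.75% of 8916 others (Fisher's exact odds ratio 4.92, p = 4.09e-278). A summit between divergent starts can make both genes count as bound, so the genes are not independent and the definition can raise the odds ratio. Genes with more annotated starts also have more chances to count as divergent and as bound, and this was not matched. The p-value therefore does not measure the strength of this difference. Of 1754 promoter summits, 832 (47.4%) lay between divergent protein-coding starts.

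Sequence alone did not mark the bound sites. Of 1603 TATCGATA sites within 500 bp of a transcript start, 45.04% had a reproducible summit within 100 bp (exact 95% interval 42.6 to 47.5%), against 1.33% of 2554 sites elsewhere (interval 0.924 to 1.86%; Fisher's exact p = 2.47e-300). Outside promoters, 23.5% of 170 peaks had TATCGA, against 59.5% of promoter peaks (Fisher's exact p = 1.29e-19). CAGCTG was present at 8.27% of promoter peaks and 3.53% of the others (Fisher's exact p = 0.0247). It was present at 9.14% of peaks with TATCGA and 6.18% of peaks without it (Fisher's exact odds ratio 1.53, p = 0.0168). These values were not adjusted for the number of comparisons.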
